A study of Mus musculus with 3 samples.

How the data were processed

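Open chromatin was measured in single mouse kidney cells by mtscATAC-seq, an assay in which cells are fixed and permeabilised so that the mitochondria stay inside and transposase marks accessible DNA. The mice carried a point mutation in the mitochondrial gene for the glutamate tRNA, given as trnE in the labels, at a stated load, the percent of mitochondrial genomes with the mutation. There were 3 libraries. Old replicate 1 came from a 75-week-old mouse kidney at 75% load, old replicate 2 from a 75-week-old kidney at 80% load, and the young library from a 3-week-old kidney at 80% load. Groups were taken from the sample titles. Sex is not given in the sources used here. The labels do not say that the old samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. No sample without the mutation was used here, and the mutation load itself was not analysed here.

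Per the submitters' processing notes and the file headers, the authors used Cell Ranger ATAC 2.1.0 on the mouse build mm10. The deposited tables hold raw counts of transposition events per peak and barcode, with peaks called on each library alone, no normalization and called cells only. Most values in the deposited counts were even, 94.3% in old replicate 1, 90.9% in old replicate 2 and 89.5% in the young library, because both ends of a fragment are counted. Intervals on counts were therefore computed on fragments, the count over 2 rounded up. This was decided after the values had been seen, as was the use of these intervals for immune cells. All intervals are exact 95% intervals (Clopper-Pearson for shares) and cover counting error only. Where a class had 0 cells in a library, a limit of 3 cells was used. A gene or region count of 0 was replaced by 3 counts, which is not on the fragment scale. Folds against such a count are values at that setting and not 95% limits.

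Peaks of the libraries were merged where they overlapped by at least 1 bp (bedtools 2.31.1), which gave 250005 merged regions. The 72317 with a peak in every library are called common regions, and a library's count in one is the sum over its own peaks there. They held 67.4%, 82.1% and 82.7% of the counts of old replicate 1, old replicate 2 and the young library. Another 44981 regions had a peak in old replicate 2 and the young library but not in old replicate 1. These entered only the alternative with all merged regions. Old replicate 1 was mostly immune cells, so common regions may under-represent chromatin open in tubule cells alone. Barcodes with at least 1000 counts in peaks were kept. Doublets were scored per library against simulated doublets with 50 neighbours, and the highest scores were removed at 0.8% of barcodes per 1000 barcodes. This left 5315, 3950 and 3976 cells in old replicate 1, old replicate 2 and the young library, after removal of 248, 133 and 135 barcodes. Common regions open in at least 1% of cells (70321) were binarised and reduced by latent semantic indexing to 30 components without the first. A graph of 20 neighbours was clustered by the Leiden method at resolution 1.0, giving 23 clusters (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, seed 7).

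Clusters were named from 20 marker sets fixed before the data were examined, covering proximal tubule, podocyte, parietal epithelium, thin limb, thick ascending limb, distal convoluted tubule, connecting tubule, principal cell, intercalated cell, endothelium, fibroblast or mesangium, smooth muscle or pericyte, macrophage or dendritic cell, T or NK cell, B or plasma cell, neutrophil, urothelium, nephron progenitor, proliferating cell and injured proximal tubule. The 6 sets from thin limb to intercalated cell were joined as loop to collecting duct, and the progenitor, proliferating and injured sets did not name a cluster. A marker was raised at a log2 fold of at least 1 over the lower quartile of clusters (pseudocount 5 CPM) and at least 10 CPM. A name needed at least 3 raised markers, a margin of 0.25 on the log2 scale over the next class, and no more markers of another class than of its own among the 10 leading genes (at least 30 CPM). A cluster of low counts with none of its own markers among those genes stayed without a name. The scoring rule was revised once after the clusters had been seen: leading genes no longer included predicted genes and clones, low counts were judged against the cell's own library, and the margin was set. Before the revision clusters 9 and 17 had no name and cluster 14 was called proximal tubule-like. After it cluster 9 was loop to collecting duct-like, cluster 17 was B or plasma cell-like and cluster 14 had no name. The revision decided that loop to collecting duct-like cells could be tested. The clusters without a name were 13, 14, 20 and 22. Cluster 13 held 0.263% of old replicate 1, 7.67% of old replicate 2 and 1.84% of the young library. Cluster 14 held 2.56%, 5.97% and 0.352% of all cells in the same order, and 45.6%, 6.16% and 0.396% of nephron epithelium. Nephron epithelium here joins proximal tubule-like and loop to collecting duct-like cells with clusters 13 and 14. Cluster 20 held 0 of 5315 cells of old replicate 1 (up to 0.0564%), 0.228% and 1.58%, and cluster 22 held 0.602%, 0.253% and 0.126%.

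Gene accessibility is the count in common regions over a gene body and 2 kb at both ends. The gene table used (GRCm38.p6, the coordinates of mm10) gives no strand, so the planned flank on the upstream side alone was replaced, and promoters, exons and introns were not told apart. Of 34614 protein-coding and lncRNA genes of the table on the autosomes, X and Y, 22959 had a common region. Overlapping genes and neighbours that share a region have the same counts and are not independent. Counts were summed per library and class, and old was tested against young with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM, filterByExpr, prior count 2), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes, regions, class shares and the difference between classes are from this test. With 2 old libraries and 1 young there is 1 residual degree of freedom, the spread comes from the old pair and from sharing over genes, and the lone young library is assumed to vary like the old. An exact permutation of 2 against 1 cannot go below p = 0.333. Classes with at least 50 cells in every library were tested, proximal tubule-like and loop to collecting duct-like cells. Endothelium-like cells, with 41 cells in the young library, were added after the data were seen.

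The test was tested on simulated counts with 200 changed genes or regions, all drawn from those above the median level. For genes, 34% of those changed by 1 on the log2 scale and 98% of those changed by 2 were called in proximal tubule-like cells, 37% and 94% in loop to collecting duct-like cells and 33% and 84% in endothelium-like cells. For regions, 0% and 51% were called in proximal tubule-like cells, 0% and 24% in loop to collecting duct-like cells and 6% and 69.4% in endothelium-like cells. Among unchanged genes 7 of 22754, 5 of 20618 and 13 of 16051 were called in those classes. The simulation drew all libraries with the same fitted spread and no difference in cell mix. It thus takes for granted that the young library varies like the old ones, and does not show how many false calls the real libraries give.

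Gene lists were tested with camera (limma 3.58.1) on log2 CPM with an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a class, and again with an estimated correlation. There were 21 lists: cell cycle, circadian clock, dissociation and immediate early response, electrolyte transport of the distal nephron, extracellular matrix and fibrosis, fatty acid oxidation, female-biased kidney genes, inflammatory and chemokine genes, interferon and antigen presentation, kidney tubule injury, male-biased kidney genes, mitochondrial aminoacyl-tRNA synthesis, mitochondrial DNA maintenance and biogenesis, mitochondrial integrated stress response, nephron development factors, nuclear OXPHOS subunits, postnatal growth and imprinted genes, proximal tubule transport, senescence, sex steroid and growth hormone receptors, and xenobiotic and oxidative stress response. The list symbols Bmal1, Ctgf, Mx1 and Zac1 (4 in all) had no gene in the table.

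Genes named in the text follow a rule fixed before the data were examined: per class and direction the 10 largest changes among genes past the threshold, at or above the median level, with both old libraries on the same side of the young one, and not a predicted gene, clone, microRNA or pseudogene. Where fewer than 5 passed, the rule was applied without the threshold. List members with the 2 smallest p-values and the 2 highest levels were named too. Predicted genes and low genes past the threshold fall outside the rule and were chosen after their values were seen, as was the set of replication-dependent histone genes. Before the data were examined the tests, lists, markers, named-gene rule and alternatives were also fixed. The alternatives were DESeq2 size factors (RLE), DESeq2 1.42.0's Wald test, no filter on low counts, no doublet removal, at least 3000 counts per cell, all merged regions with a missing peak counted as 0 (the union), thinning each class to its smallest library, leaving out each old library, Leiden resolutions of 0.5 and 2.0, clustering each library alone, and stricter peak sets and overlaps. Regions within 1 kb of either gene end, the estimated correlation in counts of lists, proximal tubule-like clusters with at least 10 cells of every library (11 and 18, the shared clusters) and endothelium-like cells were added after the data were seen. Motifs in regions and promoters alone were planned and not run, since neither a genome nor gene strands were used here.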

Results

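Open chromatin was profiled in mouse kidney cells with a mutation of the mitochondrial glutamate tRNA gene, in 2 libraries at 75 weeks of age and 1 at 3 weeks. The mutation load was 75% in old replicate 1 and 80% in old replicate 2 and the young library. The libraries held 5656, 4302 and 4440 barcodes, in the order old replicate 1, old replicate 2 and young, which holds for all values given in threes below. The median per barcode was 16288.5, 13338.5 and 23319.5 counts, and 5315, 3950 and 3976 cells were kept. The young group has no replicate, so errors rest on the pair of old libraries. Unless another tool is named, adjusted p-values are two-sided and come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

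Peak sets were compared first, to show which regions were open with age and which in single libraries. The peaks of old replicate 2 and the young library overlapped most: 82.8% of the 143258 peaks of old replicate 2 had a young peak, and 79.4% of the 149490 young peaks had a peak of old replicate 2. Old replicate 1 stood apart, since 47.4% of its 169187 peaks were met by old replicate 2 and 49.9% by the young library. It covered 55.6% of the peaks of old replicate 2 and 56.3% of the young peaks, and with only peaks open in at least 2% of barcodes these shares were 35.6% and 32.6%. Of the merged regions, 78112 were called in old replicate 1 alone, 18179 in old replicate 2 alone and 19872 in the young library alone. Regions called in both old libraries and not in the young one were the smallest group, with 6093 (2.44%). Immune cells gave 96.0% of the counts of old replicate 1 in the regions called there alone, against 90.0% of all its counts. Peak number depends on depth and on the cells in a library, so no test was made.

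Cell classes were compared to show whether the make-up of the kidney suspension changed with age. The libraries held very different cells, and for immune-like cells the old pair lay furthest apart. Immune-like cells were 90.6% of old replicate 1 (95% interval 89.8% to 91.4%), 0.228% of old replicate 2 (0.104% to 0.432%) and 8.43% of the young library (7.58% to 9.33%). Proximal tubule-like cells, which reclaim filtered solutes, were 1.81% (1.47% to 2.20%), 75.2% (73.8% to 76.6%) and 81.4% (80.2% to 82.6%). Loop to collecting duct-like cells, the distal segments that adjust salt and water, were 0.978% (0.732% to 1.28%), 8.15% (7.32% to 9.05%) and 5.23% (4.56% to 5.97%). Endothelium-like cells were 3.16%, 2.28% and 1.03%. Among the immune classes, macrophage or dendritic-like cells were 61.6%, 0.101% and 2.99%, and T or NK-like cells were 23.1%, 0.0506% and 1.86%. Neutrophil-like cells were 3.12%, 0.0759% and 0.377%. B or plasma-like cells were 2.80% of old replicate 1 and 3.19% of the young library, with 0 of 3950 cells in old replicate 2, which allows a share of up to 0.0759%.

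Within the immune cells, B or plasma-like cells were 37.9% in the young library and 3.09% in old replicate 1, and macrophage or dendritic-like cells were 35.5% and 67.9%. T or NK-like cells were 22.1% and 25.5%, and neutrophil-like cells 4.48% and 3.45%. Among non-immune cells, proximal tubule-like cells were 19.3%, 75.4% and 88.9%, endothelium-like cells were 33.7%, 2.28% and 1.13%, and loop to collecting duct-like cells were 10.4%, 8.17% and 5.71%, above the young share in both old libraries. No class share passed the test of old against young (adjusted p from 0.905 to 0.962 over 8 classes), and an exact permutation cannot go below 0.333 here. The log2 ratio of old over young was 3.36 for macrophage or dendritic-like, 2.64 for T or NK-like, 2.08 for neutrophil-like, 1.40 for endothelium-like, -1.08 for proximal tubule-like, -0.20 for loop to collecting duct-like, -1.19 for B or plasma-like and 1.17 for cells without a name. Without old replicate 1 it was -4.89, -5.20 and -2.31 for the first 3 of these, 0.64 for loop to collecting duct-like cells and -0.11 for proximal tubule-like cells. Without old replicate 2 it was -5.49 for proximal tubule-like cells, -2.42 for loop to collecting duct-like cells and -0.19 for cells without a name. Immune cells fill most of old replicate 1, so its low shares of tubule classes among all cells depend on that denominator. Podocyte-like cells formed a class of their own at Leiden resolution 2.0, with 23, 19 and 9 cells.

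**Figure D1:**
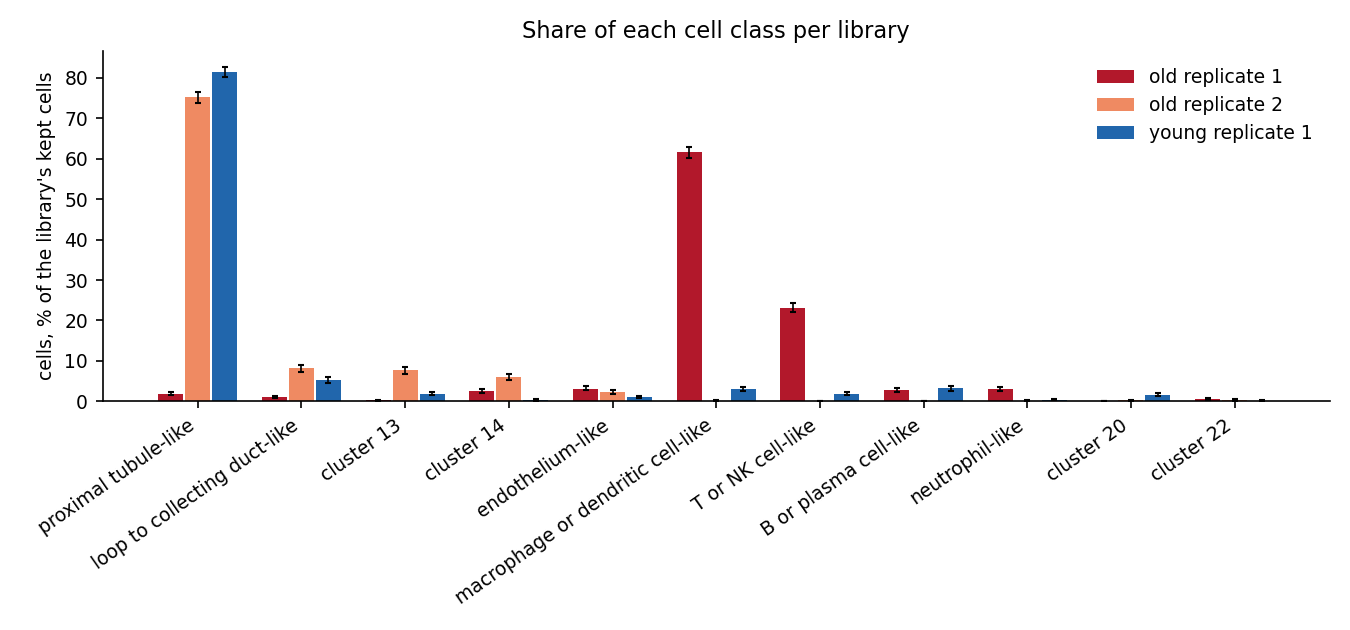
Share of each cell class in percent of the kept cells of a library (bars, with exact 95% intervals), for old replicate 1 in dark red, old replicate 2 in orange and the young library in blue. Macrophage or dendritic-like cells reached 61.6% of old replicate 1, while proximal tubule-like cells were 75.2% of old replicate 2 and 81.4% of the young library.

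Proximal tubule-like cells were compared between old (96 and 2971 cells) and young (3237 cells) to find which genes opened or closed with age in this class. The histone genes H2bc8, H2bc9 and H3c7, of the replication-dependent kind that is expressed in S phase, fell in the old libraries. H2bc8, a histone H2B gene on chromosome 13 at 23571400 to 23571863, fell by 2.58 on the log2 scale (SE 0.40, adjusted p = 0.00111), from 43.3 CPM in the young library to 7.76 and 7.04 CPM in old replicates 1 and 2. H2bc9 and H3c7, neighbours on chromosome 13 (23542923 to 23543444 and 23544052 to 23544954) with the same counts, fell by 1.79 (SE 0.32, adjusted p = 0.00569). H1f7, the linker histone gene of spermatids (chromosome 15, 98255982 to 98257307), rose by 2.98 (SE 0.46, adjusted p = 0.00111), with 35.6, 29.2 and 4.03 CPM. Prex2, which encodes an exchange factor for Rac (chromosome 1, 10993273 to 11303683), rose 3.59-fold (log2 1.84, SE 0.37, adjusted p = 0.0267), with 38.8, 40.8 and 11.1 CPM.

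Old and young cells of this class lay mostly in separate clusters: clusters 0 and 5 held 26, 1399 and 1 and 8, 882 and 1 cells, and clusters 2, 6 and 8 held 1196, 776 and 690 young cells and none of old replicate 1. Clusters 11 and 18, the only ones with at least 10 cells of each library, held 56, 583 and 113 cells. Whether the separation into clusters reflects segment, age or library was not tested. Cluster 11 held 37, 395 and 58 cells and cluster 18 held 19, 188 and 55. This mix differed between libraries and was not held fixed in the fit that follows. A fit within these clusters alone, added after the data were seen, kept 9 of the 10 calls below, with -3.14 at H2bc8 (adjusted p = 0.00113), -2.13 at H2bc9, 3.15 at H1f7 and 2.70 at Prex2 (adjusted p = 0.00125), and called 44 genes higher and 8 lower of 21321.

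In all, 7 genes rose and 3 fell of 22959 tested (358 at an unadjusted p under 0.05), and DESeq2 called 7 higher and 0 lower, of which 6 were shared. The other 5 that rose were predicted genes. Gm33272 on Y (90793687 to 90806846) rose 3.63-fold (SE 0.30 on the log2 scale, adjusted p = 0.00191), with 192, 174 and 50.1 CPM. Gm34712 rose by 2.31 (SE 0.37), Gm30944 by 1.72 (SE 0.31), Gm32663 by 2.89 (SE 0.57) and Gm52557 by 3.47 (SE 0.62), where Gm52557 rose by 2.85 without old replicate 1. The largest differences at higher levels that did not pass the threshold were Xkr4 (log2 1.53, SE 0.32, adjusted p = 0.0518), Snrpn (1.41, SE 0.36), Snhg14 (1.34, SE 0.35), Rxrg (1.32), Hoxc10 (1.31), Lncpint (1.27, SE 0.29), Cdsn (1.27), Pnck (1.21), Eed (1.16) and Il1rapl1 (1.13). On the lower side these were Inafm1 (-1.17), Eva1b (-1.16), H2ac10 (-1.12), Ptpn14 (-1.11), Arhgef17 (-1.07), H4c8 (-1.06), Grid1 (-0.92) and T2 (-0.91). Rxrg leads cluster 5 and Hoxc10, Pnck and Il1rapl1 lead cluster 11, and within the shared clusters their values were 0.29, 0.75, 0.68 and 0.47, while Xkr4 and Lncpint had 1.86 and 1.42 (adjusted p = 0.0213 and 0.00647). In the union of peaks, in which a missing peak counts as 0, none of the 10 called genes passed. H2bc8 ranged in adjusted p from 1.69e-06 with RLE to 0.444 with the union (0.0513 with DESeq2), H1f7 from 1.69e-06 to 0.414, and Prex2 from 0.00125 within the shared clusters to 1.00.

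Of 72315 regions, 30 rose and 5 fell (1211 at an unadjusted p under 0.05), and DESeq2 called 11 higher and 0 lower (419 unadjusted). Regions that rose lay in Alk (chromosome 17, 72448233 to 72449188, log2 3.48, SE 0.50, adjusted p = 0.000481), in Mapre2 (chromosome 18, 23781625 to 23782536, 3.54, SE 0.60) and in the imprinted Snhg14 and Snrpn locus (chromosome 7, 60351933 to 60352871, 3.70, SE 0.66, adjusted p = 0.00534). Others were on chromosome 1 at 73111537 to 73112484 (3.96, SE 0.64) and chromosome 8 at 86766521 to 86767636 (3.87, SE 0.58), at 26101 and 19461 bp from the nearest gene. Of the 5 regions that fell, 3 covered histone genes: H2bc7 with H2ac7 (chromosome 13, 23573821 to 23574747, -2.84, SE 0.57), H2ac15 with H2bc15 (21753479 to 21754391, -2.72, SE 0.54) and H2ac8 with H2bc8 (23570802 to 23571734, -2.51, SE 0.48). The others lay in Speg (chromosome 1, 75399740 to 75400493, -2.60, SE 0.53) and on chromosome 6 at 51170333 to 51171408 (-2.74, SE 0.46, 3887 bp from Gm32328).

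**Figure D2:**
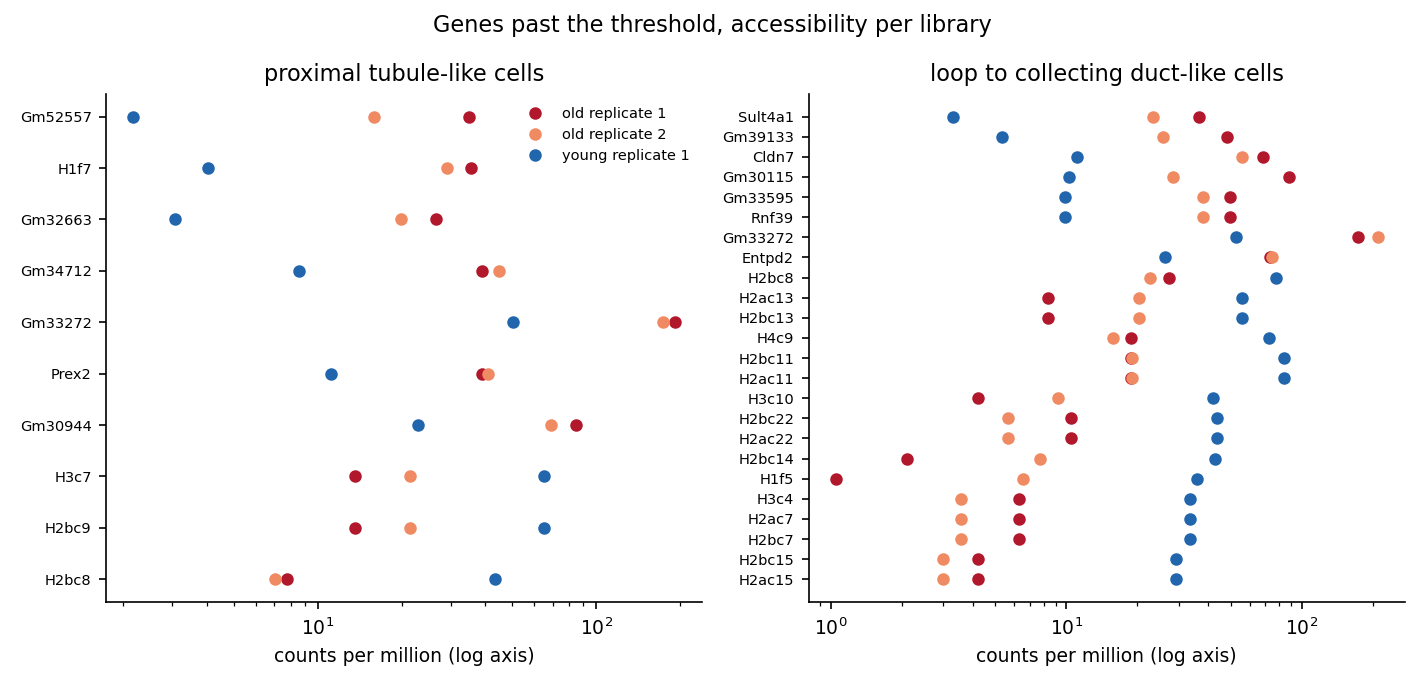
CPM (log axis) of each gene past the threshold in proximal tubule-like and loop to collecting duct-like cells, 1 point per library (old replicate 1 dark red, old replicate 2 orange, young blue). Both old libraries lie on the same side of the young one for each gene drawn, as for Gm33272 at 192, 174 and 50.1 CPM in proximal tubule-like cells, and Gm46526 is left out because its young count was 0.

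The genes of interferon and antigen presentation rose as a group in proximal tubule-like cells, with 21 of 22 above 0 (median 0.25, mean 0.39, camera adjusted p = 0.000153). With an estimated correlation the call did not hold (adjusted p = 0.885 with an estimated correlation), and it was also lost after thinning (adjusted p = 0.343) and within the shared clusters (median 0.13, adjusted p = 0.156). Its members were not called singly: Irf1, a transcription factor of the interferon response, had a log2 change of 1.29 (SE 0.40, adjusted p = 0.765), Nlrc5, an activator of class I antigen genes, 0.41, Tap1, the peptide transporter, 0.25, and Stat2 0.24. The sex steroid and growth hormone receptor list also rose, with 10 of 17 above 0 (median 0.37, mean 0.23, camera adjusted p = 0.0356, and adjusted p = 0.885 with an estimated correlation). Its call was lost without doublet removal, at 3000 counts per cell, with the union (median -0.01), after thinning and at gene ends. Socs2 and Socs3, feedback inhibitors of cytokine signals, had 0.74 (SE 0.30) and 0.84 (SE 0.36), while the receptors Igf1r and Ghr had -0.18 and -0.13. Macrophage markers in these cells summed to 147, 120 and 114 CPM and T cell markers to 285, 333 and 344 CPM.

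Mitochondrial and metabolic lists did not pass in proximal tubule-like cells. The median was -0.04 for mitochondrial aminoacyl-tRNA synthesis (adjusted p = 0.986, mean 0.01, 11 of 23 above 0), -0.04 for mitochondrial DNA maintenance and biogenesis (0.574), 0.08 for the mitochondrial integrated stress response (0.513), 0.05 for nuclear OXPHOS subunits (0.574) and 0.11 for fatty acid oxidation (0.279). Among their members, the leucyl-tRNA synthetase gene Lars2 had 0.37 (SE 0.31), the phenylalanyl-tRNA synthetase gene Fars2 -0.31, the biogenesis coactivator gene Ppargc1a -0.05, the serine synthesis genes Psat1 and Phgdh 0.43 and -0.51, Ddit3 0.14 and the respiratory chain genes Cox5a and Ndufs1 0.38 and 0.27. Proximal tubule transport had a median of -0.11 (adjusted p = 0.304), which turned to 0.49 with an upward call within the shared clusters (adjusted p = 6.5e-07), with -0.50 at Slc22a13, -0.08 at Slc4a4 and 0.14 at Abcc4. Electrolyte transport of the distal nephron had 0.06 (0.610), xenobiotic and oxidative stress response 0.06 (0.574) and the circadian clock 0.02 (0.833).

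The other lists did not pass either, with medians of -0.14 for cell cycle (adjusted p = 0.146, 6 of 23 above 0), 0.14 for dissociation and immediate early response (0.243), -0.04 for extracellular matrix and fibrosis (0.574), 0.02 for inflammatory and chemokine genes (0.806), 0.10 for kidney tubule injury (0.610), 0.18 for male-biased kidney genes (0.146), -0.09 for nephron development factors (0.304) and -0.18 for postnatal growth and imprinted genes (0.574). Examples are the imprinted gene Peg3 (-0.83, SE 0.29, with 137, 76.6 and 183 CPM), the fetal RNA-binding protein gene Igf2bp1 (-1.10, SE 0.40), the kidney development factor gene Pax8 (-0.40), the cell surface gene Cd44 (0.99) and the chemokine gene Cxcl1 (0.69). For female-biased kidney genes the median was -0.09 and the mean 0.27 with an upward test (0.574), and for senescence the median was -0.03 and the mean 0.03 with a downward test (0.833). Over all genes 0 list members were called by edgeR. Adjusted over the list alone, 2 female-biased genes were higher, with Cyp2a4 at 3.23 (SE 0.88) and Slco1a6, an organic anion transporter gene, having the smallest p-values (Slco1a6 with 34.9, 26.1 and 10.5 CPM), and 1 transport gene was higher, where Slco1a6 is also a member.

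None of the 20 marker sets passed in proximal tubule-like cells. The medians (camera adjusted p in brackets) were 0.39 for principal cell (0.173), 0.28 for injured proximal tubule (0.51), 0.22 for smooth muscle or pericyte (0.339), 0.18 for connecting tubule and for podocyte (both 0.51), 0.16 for macrophage or dendritic cell (0.51), 0.04 for endothelium (0.884), 0.02 for parietal epithelium (0.996) and for fibroblast or mesangium (0.845), -0.00053 for nephron progenitor (0.824), -0.04 for B or plasma cell (0.51), -0.06 for T or NK cell (0.53), -0.09 for proximal tubule (0.361), -0.12 for proliferating cell and for thin limb (both 0.53), -0.22 for neutrophil (0.51) and -0.30 for urothelium (0.51). In 5 sets the test was downward while the median was positive: endothelium, fibroblast or mesangium, distal convoluted tubule (0.07, 0.824), thick ascending limb (0.05, 0.824) and intercalated cell (0.09, 0.845). The mean was positive in each of these but distal convoluted tubule (-0.0076).

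Loop to collecting duct-like cells were compared between old (52 and 322 cells) and young (208 cells) with the same question. Accessibility rose at Cldn7 and Entpd2 and fell at a block of histone genes on chromosome 13. The class pools segments, and its mix differed between libraries. At Leiden resolution 2.0 a cluster that scored highest for principal cell held 11, 55 and 15 cells. The other, which scored highest for thick ascending limb, held 42, 267 and 193. Slc12a1, a marker of that limb, had 12.4, 52.2 and 82.6 CPM. Whether this mix accounts for the changes was not tested. Cldn7, a tight junction gene of distal tubule epithelium (chromosome 11, 69964779 to 69967886), rose 5.45-fold (log2 2.45, SE 0.42, adjusted p = 0.000524), with 68.2, 55.5 and 11.1 CPM. Entpd2, an ATP-degrading surface enzyme (chromosome 2, 25395874 to 25401323), rose 2.81-fold (log2 1.49, SE 0.34, adjusted p = 0.0317), with 73.5, 74.8 and 26.4 CPM. The neighbours H2ac11 and H2bc11 (chromosome 13, 22042478 to 22042949 and 22043198 to 22043658) fell by 2.13 (SE 0.35, adjusted p = 0.000226), with 18.9, 19.1 and 83.6 CPM, and H4c9 (22040960 to 22041362) was 4.28-fold lower (SE 0.38 on the log2 scale, adjusted p = 0.000992).

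In all, 9 genes rose and 16 fell of 21273 tested (863 at an unadjusted p under 0.05), and the 16 that fell were histone genes with 10 distinct sets of counts. Beyond those above, H2bc8 fell by 1.67 (SE 0.34, adjusted p = 0.01), and the rest were H2ac7, H2bc7 and H3c4 (each -2.89), H1f5 (-2.89), H2ac13 and H2bc13 (-1.79), H2bc14 (-2.84), H2ac15 and H2bc15 (-3.10), H2ac22 and H2bc22 (-2.58) and H3c10 (-2.47). Without old replicate 1 H1f5 had -2.30, and without old replicate 2 the values were -4.24 at H1f5, -3.87 at H2bc14, -3.07 at H3c10, -2.60 at H2ac13, -2.25 at H2bc7 and -1.97 at H2ac22. Sult4a1, a brain sulfotransferase gene (chromosome 15, 84076097 to 84105754), rose by 3.12 (SE 0.68, adjusted p = 0.0195) on 35, 78 and 8 counts, and by 2.53 without old replicate 1. Gm46526, which overlaps it and had 0 young counts, was 19.2-fold higher with 3 counts in place of 0. Rnf39 and Gm33595, with the same counts, rose by 2.11 (SE 0.48), Gm33272 by 1.87 (SE 0.25, adjusted p = 1.51e-06), Gm39133 by 2.71 (2.09 without old replicate 1) and Gm30115 by 2.38 (1.39 without old replicate 1 and 2.99 without old replicate 2). At higher levels and past no threshold were Dusp8 (1.42, adjusted p = 0.0693), Tmem178b (1.39), Wdr70 (1.38), Aox2 (1.37), Eed (1.28), Pnpla1 (1.26), Celf2 (1.20) and Sbno2 (1.20, 0.0704).

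DESeq2 called 2 genes higher and 0 lower, and none of the 25 genes passed without the filter on low counts, with the union of peaks or after thinning. The adjusted p of Cldn7 ranged from 4.82e-05 with RLE to 0.771 after thinning (0.0345 with DESeq2). No region passed edgeR's test of 51629 (0 higher and 0 lower, 1178 at an unadjusted p under 0.05, DESeq2 1 higher and 612 unadjusted). With adjusted p = 1.00 in edgeR for all regions named next, Sult4a1 (chromosome 15, 84102558 to 84103696, 0 young counts) was 18.5-fold higher with 3 counts in place of 0. Ratios were 56.7 (4.86 to 1140) in Nr1d2, 48.6 (4.19 to 992) in Ski, 37.3 (3.11 to 781) near Pnpla1 and 23.6 (3.97 to 959) in Bach2, each on 1 or 2 young counts. The 5 lowest were -3.21 on chromosome 6 (51178080 to 51179033) and -3.15, -2.96, -2.94 and -2.91 in histone regions of chromosome 13.

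Proximal tubule transport genes fell as a group in loop to collecting duct-like cells, with 9 of 27 above 0 (median -0.34, camera adjusted p = 0.0343, and adjusted p = 0.879 with an estimated correlation). The call was also lost without doublet removal, after thinning, at gene ends and with DESeq2. Slc2a2, the basolateral glucose transporter gene, had -0.79, Slc4a4 -0.20, Abcc4 0.21 and Slc3a1, an amino acid transport gene, 0.89, none past the threshold. Proximal tubule markers summed to 245, 190 and 240 CPM in these cells and injured proximal tubule markers to 336, 258 and 225 CPM, while the loop gene Slc12a1 had 12.4, 52.2 and 82.6 CPM. Background from proximal tubule-like cells was not estimated here.

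None of the other lists passed in this class. The medians (camera adjusted p in brackets) were -0.23 for cell cycle (0.143), -0.09 for circadian clock (0.556), 0.11 for immediate early response (0.735), -0.02 for distal electrolyte transport (0.556, mean 0.08), 0.03 for matrix (0.735), 0.01 for fatty acid oxidation (0.810, mean 0.02 with a downward test), -0.10 for female-biased genes (0.728), 0.25 for inflammatory genes (0.158), 0.24 for interferon and antigen presentation (0.556), 0.24 for tubule injury (0.143) and 0.01 for male-biased genes (0.735). They were -0.03 for aminoacyl-tRNA synthesis (0.735), -0.13 for mitochondrial DNA maintenance (0.556), 0.04 for the integrated stress response (0.689), 0.04 for nephron development (0.735, mean -0.0054 with a downward test), -0.12 for OXPHOS subunits (0.556), -0.09 for postnatal growth (0.556), 0.0006 for senescence (0.700), 0.0036 for sex steroid receptors (0.981) and -0.06 for xenobiotic response (0.661). Examples are Peg3 (-0.71, SE 0.21, adjusted p = 0.494), Pax8 (-0.65, 0.965), Socs3 (1.14, 0.561), the proliferation genes Mcm3 and Mki67 (-0.50 and -0.74), the clock genes Nr1d1 and Hlf (-0.45 and -0.46), the stress genes Atf4 and Chac1 (-0.59 and 0.85) and Psmb8 of the immunoproteasome (0.97). Over all genes 0 members were called, and adjusted over the list alone 1 gene each was higher in the injury list (Sox9, with 0 young counts) and the steroid receptor list, and 1 was lower in the growth list. None of the 20 marker sets passed: the lowest adjusted p was 0.3, for proximal tubule (median -0.44) and proliferating cell (-0.31, 0 of 6 above 0), and principal cell had 0.39 (0.38).

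Endothelium-like cells had 168, 90 and 41 cells. Accessibility rose at Eng, Alpl, Opa3 and Synpo and fell at Auts2. Eng, the endoglin gene of endothelial BMP and TGF-beta signalling (chromosome 2, 32646595 to 32682669), rose 6.06-fold (log2 2.60, SE 0.45, adjusted p = 7.99e-05), with 151, 96.1 and 20.7 CPM. Alpl, the tissue-nonspecific alkaline phosphatase gene (chromosome 4, 137741731 to 137796384), rose by 2.34 (SE 0.46, adjusted p = 0.0017), and Opa3, a mitochondrial membrane protein gene, by 1.18 (SE 0.28, adjusted p = 0.018). Synpo, an actin-binding protein gene on the podocyte marker list (chromosome 18, 60593981 to 60660173), rose by 1.49 (SE 0.25, adjusted p = 7.88e-05), with 353, 323 and 121 CPM. Auts2 fell by 1.81 (SE 0.38, adjusted p = 0.00353), with 29.3, 40.3 and 119 CPM.

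In all, 17 genes rose and 15 fell of 16864 tested (1539 at an unadjusted p under 0.05). Other genes that rose were Zfp286os (2.17), Gm33272 (2.89, adjusted p = 5.35e-06), Slc5a3, a myo-inositol transporter gene, and predicted genes such as Gm33747. With 3 counts in place of a young count of 0, Slc5a3 was 5.18-fold and Gm33747 7.96-fold higher. On 3 young counts each, Gm33823 had a ratio of 11.7 (2.36 to 73.5) and G530011O06Rik 9.85 (1.97 to 62.2). Genes that fell were Proser2 (-3.92), Osbpl6 (-2.49), Myo5b (-2.25), Arhgap24 (-2.23), Unc5c (-2.20), Ank2 (-2.18), Clmn (-2.05), Rnf212b (-2.42), Fat1 (-2.01), Gas1 (-1.93) and Slc25a21. Without old replicate 1 the values were -3.16 at Proser2, -1.70 at Osbpl6, -1.45 at Myo5b, -1.18 at Unc5c, -1.39 at Clmn, -1.54 at Rnf212b and -1.03 at Gas1, and without old replicate 2 they were -3.29 at Unc5c, -3.05 at Rnf212b, -2.92 at Gas1, -2.84 at Myo5b and, where it rose, 2.28 at G530011O06Rik. DESeq2 called 2 genes higher (Synpo and Gm33272, adjusted p = 0.0426) and 0 lower, and none of the 32 passed with the union of peaks or after thinning. Of 22612 regions 112 rose and 22 fell (2122 at an unadjusted p under 0.05, DESeq2 0 with 671 unadjusted). The first was in Col4a2, a basement membrane collagen gene (chromosome 8, 11322530 to 11324224, 0 young counts, adjusted p = 2.97e-06). It was followed by chromosome 4 at 9708282 to 9710150 and chromosome 7 near Cavin3. With 3 counts in place of 0 these were 11.3-fold, 8.36-fold and 8.30-fold higher. The lowest was chromosome 17 at 4497967 to 4498990 (-2.73, SE 0.52).

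Proximal tubule transport genes were lower as a group in endothelium-like cells too, with 3 of 19 above 0 (median -1.10, camera adjusted p = 0.00249, and adjusted p = 0.978 with an estimated correlation). The median was -1.46 in old replicate 1 and -0.57 in old replicate 2, and the call was lost after thinning and at gene ends. Slc4a4 had -1.59 (adjusted p = 0.0554) and Slc6a19, the neutral amino acid transporter gene, -2.40 (0.0871), and proximal tubule markers summed to 281, 243 and 338 CPM. Proximal tubule-like cells were 1.81%, 75.2% and 81.4% of the libraries, and background from them in this class was not estimated. No other list passed, and their adjusted p ran from 0.127 for inflammatory genes (median 0.49) through 0.678 for interferon and antigen presentation (0.20), 0.812 for OXPHOS subunits (0.03) and 0.922 for aminoacyl-tRNA synthesis (0.08) to 0.994 for tubule injury (-0.14, with an upward test). The respiratory chain gene Cox4i1 had 2.18 (adjusted p = 0.071), Ppargc1a -1.16 (0.212) and the fetal gene Igf2bp3 -1.56 (0.0776). Over all genes 0 list members were called, and adjusted over the list alone 4 lists had 1 higher (distal transport, matrix, nephron development, OXPHOS), distal transport and growth had 1 lower each and proximal tubule transport had 2 lower. Of 19 marker sets measured none passed, with the lowest adjusted p at 0.0552 for parietal epithelium (median -1.20) and proximal tubule (-0.79).

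Replication-dependent histone genes were then taken as a set, chosen after members had been seen among the calls. In proximal tubule-like cells 51 of 59 were lower, with a median of -0.52 (-0.58 in old replicate 1 and -0.49 in old replicate 2) and 3 called. Of the same set 53 of 59 were lower in loop to collecting duct-like cells, with a median of -0.70 (-1.01 and -0.75), also -0.70 with the 3 genes of 0 old counts at their bound. In endothelium-like cells 37 of 54 were lower, with a median of -0.35 (-0.34 and -0.27) and 0 called by edgeR. The replication-independent histone genes had medians of -0.06, -0.10 and -0.10. All alternatives kept the sign of the set's median, with -0.27 in proximal tubule-like cells at gene ends and -0.43 within the shared clusters, and DESeq2 called 0 of these genes lower. Neighbouring genes share regions, so the genes are not independent, and reads shared between near-identical copies were not examined.

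**Figure D3:**
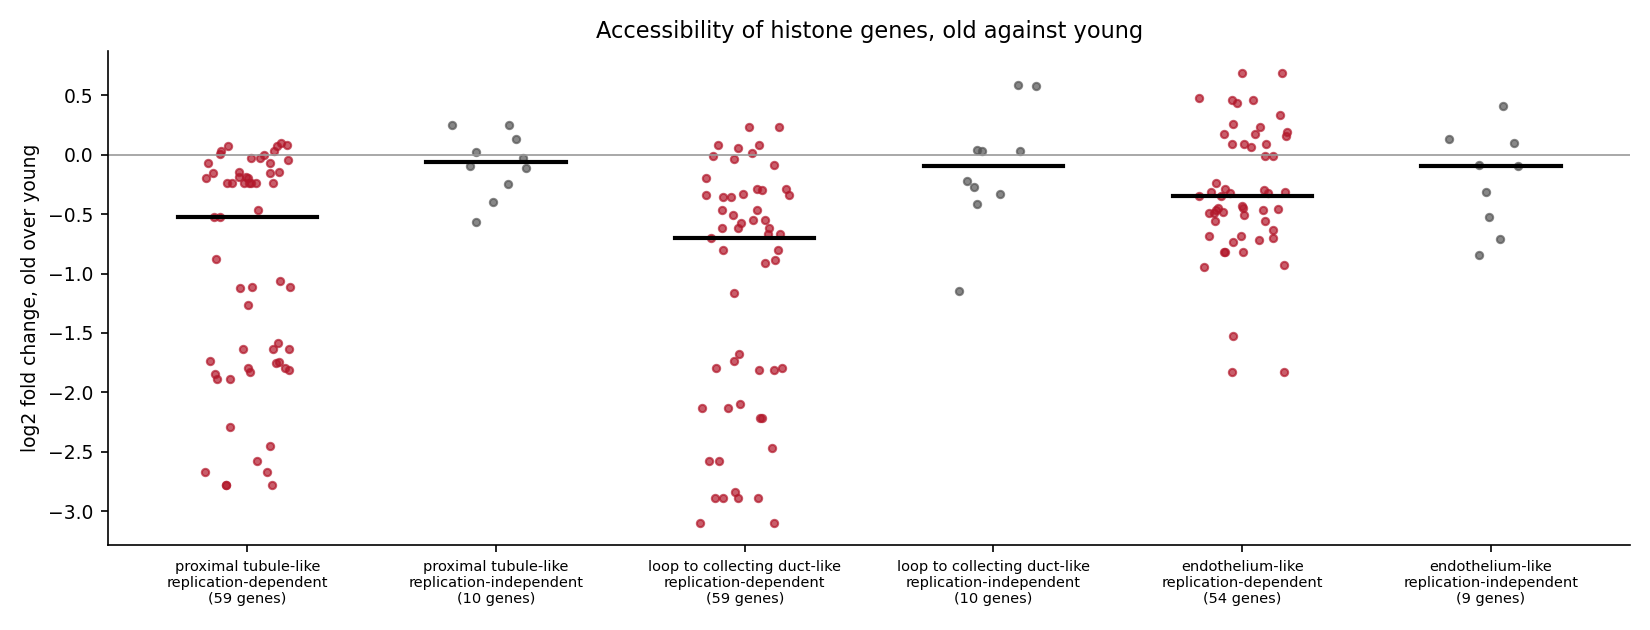
Log2 fold change of old over young (vertical axis) of each replication-dependent (red) and replication-independent (grey) histone gene in 3 classes, with a black line at the median over all genes of the set. The medians of the red sets are -0.52, -0.70 and -0.35, and 3 genes with 0 counts in both old libraries (H2ac23, H2bc23 and H4c17, loop to collecting duct-like cells) are in the median and not drawn.

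The age effect was next compared between loop to collecting duct-like and proximal tubule-like cells, with library as a block. The histone genes H2ac11, H2bc11 and H4c9 fell in loop to collecting duct-like cells and not in proximal tubule-like cells, where their log2 values were 0.08, 0.08 and 0.10. The difference between classes was -2.18 for H2ac11 and H2bc11 (adjusted p = 0.0278) and -2.18 for H4c9 (adjusted p = 0.0493). These 3 of 22378 genes, which share regions, passed, with 0 in the other direction (544 at an unadjusted p under 0.05). With the union of peaks none passed. The mix of segments in loop to collecting duct-like cells, which differed between libraries, was not held fixed. Prex2 was next, with -2.94 (adjusted p = 0.751).

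The old libraries at 75% and 80% load were set side by side without a test, since the old group has 1 sample at each load. The load of old replicate 1 is itself in doubt: its label states 75%, while the name of its deposited table points to 80%. In proximal tubule-like cells against the young library, nuclear OXPHOS subunits had a median of 0.11 at 75% load (23 of 30 above 0) and -0.05 at 80% load (9 of 30). Mitochondrial DNA maintenance had 0.10 and -0.11, aminoacyl-tRNA synthesis 0.01 and -0.08, and the mitochondrial stress response 0.14 and 0.02. Fatty acid oxidation had 0.26 and -0.04, immediate early response 0.35 and -0.06, and extracellular matrix -0.53 and 0.06. Interferon and antigen presentation had 0.35 and 0.21, and the sex steroid and growth hormone receptors 0.36 and 0.35. The values of old replicate 1 rest on 96 cells, of which 56 lay in clusters 11 and 18, against 583 of 2971 in old replicate 2. The mix of clusters was not held fixed, so these values do not separate load from the kinds of cells sampled.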

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

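All tests on the immune cells and on cluster 14, and the depth test in loop to collecting duct-like cells, were chosen only after the result was seen, as were the old replicate 2 control on dividing cells and the matched comparison in the proximal tubule depth test. The histone genes H2ac11, H2bc11 and H4c9 stood out because their age effect differed between classes. It was lower in loop to collecting duct-like than in proximal tubule-like cells by -2.18 for H2ac11 and H2bc11 (adjusted p = 0.0278, edgeR) and by -2.18 for H4c9 (adjusted p = 0.0493). In loop to collecting duct-like cells both old libraries were below the young one. The 3 genes lie within 3 kb and share regions, so they count as a single place, and none passed with the union of peaks.

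Immune cells made up 90.6% of old replicate 1. Carry-over of cells under the same barcode is argued against, because 23 of its immune barcodes were also cells of the young library. Chance, estimated from barcodes shared by old replicate 2 and the young library, gives 35.8 and an upper limit of 48. Cells mixed before they received barcodes would not be seen this way. Old age alone is argued against by the other old library, with 0.228% immune cells, below the 8.43% of the young library. Loss of tubule cells cannot be told apart: old replicate 1 had 3.51 times as many immune cells per endothelial cell as the young library (95% counting interval 2.39 to 5.06), but the libraries had 28.7, 0.1 and 8.17, so old replicate 2 and the young library lie further apart than that. Open remain other tissue in the suspension or an enrichment of immune cells, which cannot be told apart from an infiltrated kidney because no table holds a value that separates them (nephron cells were 5.61%), and a biological difference of this sample, whose load is itself in doubt, which was not tested.

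Replication-dependent histone genes were less accessible in old tubule cells. In loop to collecting duct-like cells a difference in depth cannot be told apart. After thinning the median of the set was -0.68 with 46 of 53 genes lower, against -0.62 for the same genes before. Thinning counts within fixed peaks leaves expected ratios nearly alike, and peaks were not called again at equal depth. The test therefore could not show an effect of depth through the peaks called in each library. No single gene passed after thinning in this class, so the single calls are not covered. In proximal tubule-like cells a difference in depth cannot be told apart either. There the median after thinning was -0.38 with 41 of 53 lower, past the bound of -0.5 set beforehand. The same genes had -0.24 before thinning, so that bound does not decide. A few dividing cells in the young library cannot be told apart either, as the spread of histone counts over its proximal tubule-like cells was above all matched gene sets (percentile 100, variance over mean 1.62 against a median of 1.33), and so was that of old replicate 2 (1.60 against 1.46); the excess was larger in the young library, but a percentile at its limit and 1 library on each side do not decide. A change of all cell types with age cannot be told apart: in macrophage or dendritic-like and T or NK-like cells of old replicate 1, with 1 library on each side, the medians were -0.09 and -0.09 (the higher percentile 0.4, under the bound of 5 set beforehand), but 41 and only 33 of 59 genes were lower, so the members go both ways in T or NK-like cells, while B or plasma-like cells had -0.19 with 37 of 53 lower (percentile 0). Endothelium-like cells, compared with both old libraries, had a median of -0.35 with 37 of 54 lower (percentile 0) and 0 called. Lower values of the set were thus not confined to tubule cells. Reads shared between copies and growth at 3 weeks of age were not tested.

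Cluster 14, with 136, 236 and 14 cells, stood apart from proximal tubule-like cells. At Leiden resolution 2.0 the cluster with most of the same leading genes held 113, 222 and 5 cells. A podocyte-like cluster of 23, 19 and 9 cells appeared there. Nupr1, among its leading genes, was also higher in cluster 14. Whether podocyte-like cells were part of cluster 14, and moved the list values below, was not tested. Doublets with immune cells are argued against, since its immune marker level in old replicate 1 lay 10.6% of the way from tubule cells of old replicate 2 to immune cells, and old replicate 2 held 236 of its cells beside 9 immune cells. A response to the dissociation of the tissue is a candidate explanation, because the immediate early list was above proximal tubule-like cells in both old libraries (medians 0.15 and 0.30, percentiles 99.4 and 100 of matched lists). An injured state cannot be told apart from it: the tubule injury list was at percentile 100 in old replicate 2 (median 0.41, 14 of 16 genes) but at 86.8 in old replicate 1 (0.19). Neither is singled out, since other lists were high in both old libraries: inflammatory and chemokine genes (medians 0.42 and 0.41, percentiles 99.85 and 100), matrix (98.73 and 99.97) and senescence (99.38 and 99.8). Proximal tubule transport was low in both (-0.30 and -0.27, percentile 0), and the injury marker Havcr1, near the floor, had 9.14 and 12.5 CPM against 0 and 2.43 in proximal tubule-like cells.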

How the results depend on the processing

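The estimated correlation over lists, the regions at gene ends, the proximal tubule-like clusters shared by all libraries and the endothelium-like class are tests chosen only after the data were seen, and the other alternatives were planned. The sets of replication-dependent histone genes kept the sign of their median under all alternatives in each class. Values below stand after the count as first given, in brackets, and where counts differ the cause was not tested, except that a filter, thinning or fewer cells changes how many genes are tested. In proximal tubule-like cells the genes higher [7] were 14 with RLE, 11 without doublet removal, 2 with the union, 12 at gene ends and 44 within the shared clusters. Genes lower [3] were 16 with RLE, 0 with DESeq2 (197 at an unadjusted p under 0.05 in both directions), 11 without doublet removal, 0 with the union, 6 after thinning, 15 at gene ends and 8 within the shared clusters. Regions higher [30] were 60 with RLE, 11 with DESeq2, 146 with the union, 17 after thinning and 125 within the shared clusters, and regions lower [5] were 13 with RLE, 0 with DESeq2, 3 without doublet removal, 8 at 3000 counts per cell, 61 with the union, 2 after thinning and 13 within the shared clusters. The union moved the median of all regions to -0.32 in this class, against -0.01, and to 0.25 in endothelium-like cells, where no filter moved it to 0.37.

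In loop to collecting duct-like cells genes higher [9] were 18 with RLE, 2 with DESeq2, 0 without the filter, 18 without doublet removal, 19 at 3000 counts, 2 with the union and 0 after thinning. Genes lower [16] were 0 with DESeq2, without the filter, with the union and after thinning. Regions higher [0] were 17 with RLE, 1 with DESeq2, 19 without the filter and 18 at 3000 counts, and regions lower [0] were 11 with RLE, 12 without the filter and 12 at 3000 counts. In endothelium-like cells genes higher [17] were 2 with DESeq2, 39 without the filter, 0 with the union and 0 after thinning, and genes lower [15] were 0 with DESeq2, 30 without the filter, 0 with the union, 0 after thinning and 7 at gene ends. Regions higher [112] were 0 with DESeq2, 66 without the filter, 0 with the union and 46 after thinning, and regions lower [22] were 0 with DESeq2, 10 without the filter, 34 without doublet removal, 0 with the union and 10 after thinning. Genes whose age effect was lower in loop to collecting duct-like than in proximal tubule-like cells [3] were 0 with the union.

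Lists called higher in proximal tubule-like cells [2] were 0 with an estimated correlation, 5 with DESeq2, 1 without doublet removal, 1 at 3000 counts, 1 with the union, 0 after thinning and 5 within the shared clusters, and lists lower [0] were 1 with DESeq2. The median of proximal tubule transport, -0.11 and not called, was 0.49 and called higher within the shared clusters. For loop to collecting duct-like cells lists higher [0] were 1 with DESeq2 and 2 at gene ends, and lists lower [1] were 0 with an estimated correlation, with DESeq2, without doublet removal, after thinning and at gene ends. In endothelium-like cells lists lower [1] were 0 with an estimated correlation, after thinning and at gene ends.

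Leaving out old replicate 1 or 2 gives values without a test, since no residual degree of freedom is left. The log2 ratio of class shares was then from -5.20 to 3.64 for T or NK-like, from -4.89 to 4.36 for macrophage or dendritic-like, from -2.31 to 3.05 for neutrophil-like, from -2.42 to 0.64 for loop to collecting duct-like, from -5.49 to -0.11 for proximal tubule-like, from 1.14 to 1.62 for endothelium-like and from -0.19 to 1.86 for unnamed cells. For B or plasma-like cells it was -0.19 without old replicate 2, and without old replicate 1 no value is given because old replicate 2 had 0 such cells. Adjusted p for class shares stayed between 0.885 and 0.979 in all clusterings and cell filters, while the ratio moved from -1.19 to -0.31 for B or plasma-like cells and from 1.17 to 2.88 for unnamed cells at 3000 counts, and to 2.11 and 1.93 for unnamed cells at resolution 2.0 and with each library clustered alone. With each library clustered alone no young cell was neutrophil-like, so no ratio is given there.

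Peak overlaps at a reciprocal 50% were 43.9% and 46.5% for old replicate 1 met by old replicate 2 and by young, 51.8% and 82.2% for old replicate 2 met by old replicate 1 and by young, and 52.7% and 78.7% for young met by the old replicates. With peaks in at least 2% of barcodes they were 46.0%, 49.8%, 35.6%, 94.4%, 32.6% and 79.6% in that order, and with the same number of peaks per library 48.9%, 51.7%, 48.7%, 81.8%, 51.5% and 81.9%.

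For single named genes 990 of the values in proximal tubule-like cells stayed on their side, 20 passed the threshold newly, 22 lost it and 83 changed sign uncalled or without a test moved beyond the spread. In loop to collecting duct-like cells these were 945, 6, 103 and 80, and in endothelium-like cells 950, 5, 111 and 79. None changed sign while called. List medians stayed for 193, 183 and 187 values in the same order of classes. Promoters alone and motifs were not run, and values that DESeq2 sets aside as outliers were left out. No paired analysis was possible because the labels pair no samples. Depth limits the old replicate 1 tubule classes (96 and 52 cells) and the young endothelium-like class (41 cells).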

Other observations

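Immune-like cells were compared between old replicate 1 and the young library, in values only, since 1 library stands on each side; the genes were chosen by a ranking set after the data were seen. Igf2bp3, a fetal RNA-binding protein gene that marks early-life blood cells, was less open in old replicate 1 in 3 classes. It was 7.19-fold lower in macrophage or dendritic-like cells (95% counting interval 5.50 to 9.43, 14.2 against 101.8 CPM), 8.76-fold lower in T or NK-like cells (4.93 to 15.8) and 9.65-fold lower in B or plasma-like cells (4.12 to 26.2). Igf2bp3 was also open in tubule cells, with 34.3, 52.6 and 71.1 CPM in proximal tubule-like cells of old replicate 1, old replicate 2 and the young library, and background from tubule cells in the immune level was not estimated. Sox4, a transcription factor gene of lymphocyte precursors, was 10.6-fold lower in T or NK-like cells (5.84 to 18.6) and 5.83-fold lower in B or plasma-like cells (2.89 to 12.5).

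In macrophage or dendritic-like cells Rab20 was 3.90-fold higher in old replicate 1 (2.86 to 5.34), the endocytic adaptor gene Dab2 3.94-fold (2.52 to 6.56), Depdc7 5.00-fold (2.53 to 11.6) and Rbks 3.42-fold (2.39 to 4.90). The mix within the class differed: clusters 3 and 4, led by C1q genes, held 1023 and 904 of 3273 cells in old replicate 1 and 14 and 8 of 119 in the young library, and cluster 12, led by genes such as Flt3, held 357 and 42. These ratios therefore do not separate age from the kinds of cells sampled. In T or NK-like cells Apol9b was 7.09-fold higher (2.41 to 22.8), and Pdcd1, the PD-1 gene, had a ratio of 11.1 (1.99 to 442) on 2 young counts. Arg1 was 8.92-fold lower (4.33 to 17.3). The mix differed in this class too. At Leiden resolution 2.0 a cluster led by genes such as Cd8b1 and Prf1 held 816 cells of old replicate 1 and 17 young cells. Another, led by genes such as Il7r, held 346 and 54. The T cell marker Cd3e had 61.6 and 10.1 CPM. Ratios in T or NK-like cells, also those of Igf2bp3 and Sox4, therefore do not separate age from the kinds of cells sampled. In B or plasma-like cells Tfap2a was 8.39-fold higher (3.15 to 31.5) and Faah 12.3-fold higher (3.29 to 105), on 8 and 4 young counts. This class was shallow, with a median of 5449.5 counts per cell. It held 149 cells of old replicate 1 and 127 young cells, and 131 and 59 at 3000 counts per cell. These ratios do not separate age from the kinds of cells sampled either.

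Gm33272 lies near the distal end of Y and was higher in the old libraries in each class compared. Over all cells it had 119, 156 and 43.8 CPM in old replicate 1, old replicate 2 and the young library. Its level in old replicate 1 and the young library was 102 and 35.6 CPM in macrophage or dendritic-like cells, 123 and 44.8 in T or NK-like cells and 483 and 87.6 in B or plasma-like cells. The Y genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in every library. Xist was found in every library, and in proximal tubule-like cells it had 30.5, 30.5 and 23.2 CPM. In old replicate 1 and the young library it had 43.3 and 53.6 CPM in macrophage or dendritic-like cells, 54.5 and 75.8 in T or NK-like cells and 44.4 and 46.1 in B or plasma-like cells. The 0 counts at these Y genes, beside the Xist counts, argue against male cells in any library. The place of Gm33272 on Y therefore does not show that its reads came from a Y chromosome. Reads shared between copies on X and Y were not examined.

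Each old library was also set alone against the other pair. In proximal tubule-like cells old replicate 1 against the rest gave 302 genes and 2474 regions past the threshold in edgeR's test, several times the 10 and 35 of old against young. It gave in loop to collecting duct-like cells 140 genes and 917 regions, and in endothelium-like cells 16 and 45. Old replicate 2 against the rest gave 0 genes in proximal tubule-like cells (178 at an unadjusted p under 0.05), 1 in loop to collecting duct-like and 1 in endothelium-like cells. Groups of 2 and 1 give no share of splits under 0.05. The lone side held only 96 or 52 tubule cells in the first split and the spread came from the larger libraries, so these counts do not rank the libraries by distance. In the clustering, 56 of the 96 proximal tubule-like cells of old replicate 1 lay in clusters 11 and 18, which all libraries shared. Those clusters held 37, 395 and 58 and 19, 188 and 55 cells. Cluster 0, with 26, 1399 and 1 cells, was shared with old replicate 2 and hardly with the young library.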
